A study of Mus musculus with 7 samples.

How the data were processed

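RNA was measured by sequencing in 7 tumours grown from MOC2, a mouse head and neck cancer cell line that expresses keratin 17 (K17), after injection of the cells into C57BL/6 mice. The labels place 4 tumours in a control group grown from parental cells (tumours 23, 24, 26 and 27) and 3 in a K17 knockout (K17KO) group. The titles name an edited pool for each knockout tumour, EX5 for tumour 25 and EX1 for tumours 28 and 29, and the meaning of these codes is not given in the sources used here. Per the labels' protocols, frozen tumours were pulverised, total RNA was isolated on columns and treated with DNase, and pooled libraries were sequenced on an Illumina NovaSeq. The labels do not state that each tumour came from a separate mouse, so the p-values of genes measure the spread between these tumours. The list p-values at a preset correlation do not, as described below.

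The deposited table holds raw read counts per gene, 1 column per tumour. FastQC 0.11.7, featureCounts 1.22.2 and edgeR 1.30.5, and the builds GRCm38 and mm10, are named in the submitters' processing notes without their roles. The aligner, the use of strand and the annotation are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and counts of near-identical families are uncertain (H2 genes, immunoglobulin and T cell receptor constant genes, Klr receptors, granzymes, mast cell proteases, Krt6a and Krt6b). The table has 27179 rows keyed by NCBI gene numbers. A RefSeq gene table of the same build named 25275 rows and GENCODE M21 named 18 more, and the 1886 rows without a name held 1.56% to 2.18% of the counts of a library. These rows have a gene number and stayed in the fits. Coordinates are from the RefSeq table on GRCm38.

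Library totals ranged from 25719888 to 41660819 counts. A count of 0 allows up to 3 counts, which is 0.0720 CPM, the count scaled by the library total in the deepest and 0.117 CPM in the shallowest library. Intervals of counts are exact 95% Poisson intervals and intervals of the Krt17 to Krt5 ratio are exact binomial (Clopper-Pearson) intervals. Intervals of ratios against a group of 1 to 3 counts use the Poisson interval of that group, and all cover counting error only. Every pair of libraries differed by far more than sampling noise, so each tumour was counted as 1 replicate.

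Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with group, libraries were scaled by TMM (trimmed mean of M values), and the quasi-likelihood test with robust dispersion was run with Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene given without another tool is from this test, and every adjusted p of a list given without another tool is from camera at the preset correlation described below. K17KO was compared with control in all 7 tumours without covariates. EX1 was compared with EX5 in a fit of control, EX1 and EX5 tumours, in which the single EX5 tumour was assumed to vary like the others. Standard errors of log2 fold changes were derived from the fold change and its F value. CPM values are TMM-scaled, and log2 CPM used a prior count of 2.

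The 42 gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes where at least 3 members passed the filter, which was so for 41 lists in K17KO against control. Camera compares the genes of a list with all other genes, and this preset takes them as almost uncorrelated. A small list p-value at the preset therefore does not show that a difference exceeds the spread between tumours. The estimated correlation and fry (limma 3.58.1) were run beside it. A list score is the mean log2 CPM of the tested members minus the mean of the control tumours. Of 615 list entries, 614 matched a row, 18 of them under a changed symbol. The lists share members, and the 20 immune lists have 281 entries for 262 genes. The grouping of 20 lists as immune was made after the values were seen.

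The genes named follow a rule fixed before the data were examined. They are Krt17, the 10 genes with the highest and the 10 with the lowest log2 fold change among genes with adjusted p under 0.05, average log2 CPM above 1, groups that do not overlap and an established symbol, a fixed set of 20 immune and keratin genes, and up to 4 members with the smallest p of each list described. After the values were seen, members were limited to 3 and to the lists that were called, and the other lists are given as counts. The values of 2 genes and of 1 immune list that fall under this rule are not reported here, and they stay in the fits and in the counts of genes and lists. For EX1 against EX5 the rule takes the 5 highest and 5 lowest by the same filters without the overlap condition. Malat1, Xist, Ccl8, Ccl11, Mmp9, Fscn1, Zbtb46, Thy1, Dcn, Col5a1, Fbln2, Clec10a, Fas, Pmaip1 and Snai1 fall outside the rule and were chosen after their values were seen.

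The fit was tested on simulated counts with the real means and library sizes. For K17KO against control (15604 genes), 14 of 100 genes with a true log2 change of 1 and 72 of 100 with a change of 2 were recovered, with 11 false calls. For EX1 against EX5 (17495 genes), 11 and 75 of 100 were recovered, with 4 false calls. Each simulation changed 200 genes, far fewer than were called in the data. The adjusted p is stricter where fewer genes change, so these counts do not carry over to the real fits.

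Alternatives chosen before the counts were seen were RLE size factors (the DESeq2 scaling), library totals, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, limma voom and leaving out each library in turn. Alternatives chosen after seeing the data were a covariate for detected Y-linked transcripts (over 100 counts of 4 Y-linked genes), only the libraries with or without them, the EX5 tumour alone against the controls, a covariate for the mitochondrial list score, and a per-library loess offset (span 0.5) for GC content and gene length. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

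The list tests were not run with DESeq2, limma voom, library totals or the stricter filter. Some runs of the data preceded the final fits. Stretches of 50 neighbouring genes were tested on 19 autosomes against 1000 shuffles of gene order. In simulated data for this test (14669 genes) shifts of 1 and 2 SD were recovered and a shift of 0.5 SD was not. The requirement to recover 0.5 SD was dropped after it had failed. Medians over whole chromosomes, without the genes of the lists, were compared with 1000 shuffles in the same way, and a simulated shift of 0.5 SD of 1 chromosome was recovered (14163 genes).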

Results

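The transcriptomes of 7 MOC2 tumours were compared to ask how tumours labelled as lacking K17, a keratin of stressed and proliferating epithelia, differ from parental tumours, and whether immune genes are among the differences, as the title of the series names immune evasion. The control group held 4 tumours and the K17KO group 3, of which 1 came from the EX5 and 2 from the EX1 pool. Library totals were 32722124, 41660819, 40449327 and 40497943 counts in control tumours 23, 24, 26 and 27, and 34629059, 28462584 and 25719888 counts in tumours 25, 28 and 29 labelled K17KO.

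Krt17, the gene the labels give as knocked out (NCBI gene 16667, chromosome 11, 100256215 to 100261029, GRCm38), was measured first. Its RNA was not lower in the tumours labelled K17KO. The control tumours held 39, 54, 58 and 83 Krt17 counts, which is 1.25, 1.31, 1.48 and 2.01 CPM. Krt17 RNA was thus low in the controls themselves, beside a mean of 1055 CPM of the keratin gene Krt8. The libraries labelled K17KO held 300 counts (8.42 CPM, 95% interval 7.50 to 9.43) in tumour 25, 93 counts (3.36 CPM, 2.71 to 4.11) in tumour 28 and 3851 counts (140.3 CPM, 135.9 to 144.8) in tumour 29. The log2 fold change was 5.07 ± 1.20 (SE, n = 3 against 4, edgeR adjusted p = 0.028), higher in 3 of 3 tumours. Without tumour 29 it was 1.96 (adjusted p = 0.048). The call was lost without control tumour 23, 24, 26 or 27 (adjusted p = 0.094, 0.082, 0.085 and 0.066) and with limma voom (log2 fold change 3.34, adjusted p = 0.163). Counts per gene do not show whether a transcript carries an edit, so they show neither the presence nor the absence of the knockout, and the groups are named by their labels throughout.

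**Figure D1:**
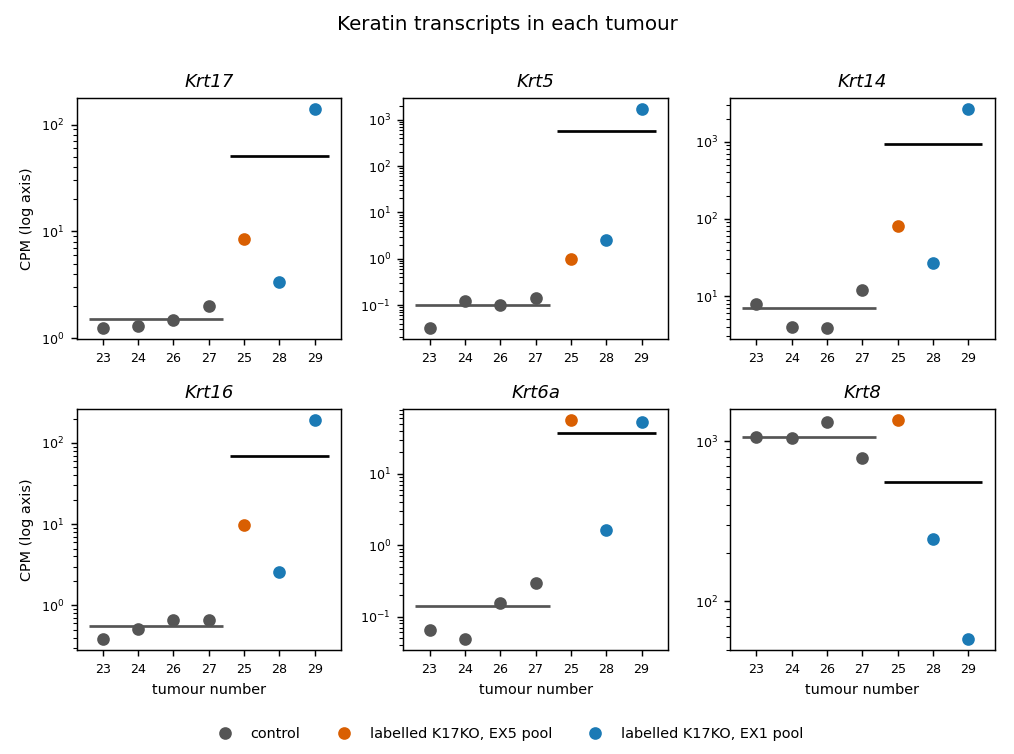
TMM-scaled CPM of 6 keratin genes in each tumour, on log axes that differ between panels. Each point is 1 tumour and horizontal lines are the means of the 4 control tumours and of the 3 tumours labelled K17KO. Krt17 lay between 1.25 and 2.01 CPM in the controls and between 3.36 and 140.3 CPM in the tumours labelled K17KO.

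The 10 highest genes in the tumours labelled K17KO included the keratins Krt5 and Krt79 and the epithelial splicing regulator Esrp1, and the 10 lowest included Dmp1 and Mycn. Among the 10 highest genes, Krt5, a basal keratin (chromosome 15, 101707069 to 101712905), had 0.100 ± 0.0488 CPM (SD, n = 4) in controls and 1.01, 2.56 and 1715 CPM in tumours 25, 28 and 29 (log2 fold change 12.39 ± 2.90 SE, edgeR adjusted p = 0.027), and 4.08 without tumour 29. Esrp1, an epithelial splicing regulator, and Fxyd3, a regulator of the sodium pump, had no count in the controls. Their means over the tumours labelled K17KO were at least 734-fold and 281-fold higher against a floor of 3 counts over the control group. Esrp1 stood at 30.9, 0.361 and 11.9 CPM in tumours 25, 28 and 29, so these folds of means do not hold for tumour 28. Pof1b and Ap1m2, both of epithelial cells, had 3 and 1 counts in the controls and ratios of means of 1143 (95% counting interval 391 to 5542) and 765 (137 to 30204). In tumour 28, Fxyd3, Pof1b and Ap1m2 stood at only 0.325, 0.325 and 0.505 CPM. The Esrp1 bound was 313-fold without tumour 25, the Fxyd3 bound 108-fold without tumour 29 and the Pof1b ratio 301 (103 to 1457) without tumour 29. Serpinb5 (maspin), Krt79, Clca3a2, Ly6g6c and Ntng1 (netrin G1) had log2 fold changes of 9.83, 9.51, 10.04, 9.20 and 9.38. Without tumour 29 these were 8.69, 3.86, 3.55, 6.48 and 9.34, and the calls of Clca3a2 (adjusted p = 0.073), Esrp1 (0.084) and Fxyd3 (0.068) were lost, as was that of Fxyd3 without tumour 25 (0.053). Of the 10 lowest genes, Dmp1, a matrix protein of bone and dentin (chromosome 5, 104197575 to 104214102), fell from 345 ± 207 to 5.46 ± 3.53 CPM (SD, log2 fold change −5.97 ± 0.77 SE, edgeR adjusted p = 0.010). Tll2, a metalloprotease, held 3 counts over the tumours labelled K17KO, a control to K17KO ratio of 136 (46.5 to 658). Mycn, a MYC-family transcription factor, fell from 23.2 ± 6.11 to 1.40 ± 0.366 CPM (log2 fold change −4.05 ± 0.34 SE, edgeR adjusted p = 0.0044). Megf10, Glp1r, Snap25, Nefl, Car8, Ptprn and Foxs1 fell with log2 fold changes from −5.74 (Megf10) to −3.87 (Foxs1). The value of Nefl was −7.43 without tumour 25, and its call was lost without any other 1 tumour (adjusted p from 0.055 to 0.098).

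Over 15604 genes, edgeR called 3334, of which 1975 were higher and 1359 lower in the tumours labelled K17KO, and 6411 genes had an unadjusted p under 0.05. The groups did not overlap in 5426 genes (34.8%, against 5.71% by chance), and 2544 genes met the filters for naming. The count rests on single libraries. It was 64, 181, 548 and 1572 without control tumour 23, 24, 26 or 27, 9018 without tumour 25, 1872 without tumour 28 and 1063 without tumour 29. Of the 112 named genes that were called, 11 kept the call without control tumour 23, 23 without 24, 48 without 26 and 81 without 27, and 110, 89 and 70 without tumour 25, 28 or 29. Dmp1, Mycn, Tll2, Foxs1, Ido1, Lat, Cd6, Klrd1, Cxcl5, Asns and Ccl11 kept it without control tumour 23 and also without 24.

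T cell and cytotoxic lymphocyte genes were higher in the tumours labelled K17KO, and the scores of both lists were higher in each of these 3 tumours than in any control tumour. All 16 T cell markers rose (median log2 fold change 3.79, camera adjusted p = 3.8e-18, adjusted p = 0.243 with an estimated correlation), and all 16 passed adjusted over the list alone. Lat, an adaptor of T cell receptor signalling, rose from 1.28 ± 0.372 to 10.03 ± 0.932 CPM (SD, n = 4 and 3, log2 fold change 2.97 ± 0.30 SE, edgeR adjusted p = 0.0061). Cd6 rose by a log2 fold change of 3.44 and the receptor gene Trbc1 by 4.65. Cd3e, a chain of the T cell receptor complex, rose from 1.48 ± 1.90 to 21.2 ± 5.17 CPM (log2 fold change 3.83 ± 0.86 SE, edgeR adjusted p = 0.025). Of 16 cytotoxic genes, 15 rose (median 3.27, adjusted p = 1.6e-11, adjusted p = 0.243 with an estimated correlation, 15 adjusted over the list alone). Cd8a and Cd8b1, the coreceptor of cytotoxic T cells, rose by log2 fold changes of 3.65 and 3.90 (edgeR adjusted p = 0.040 for both). Gzmb (granzyme B) rose by 2.81, Prf1 (perforin) by 2.66, Klrd1 by 3.71, Ctsw by 4.62 and Ifng (interferon gamma) by 3.62. Of 12 NK cell markers 9 rose (median 3.09, adjusted p = 1.7e-05, 0.283 as the adjusted p with an estimated correlation, 9 adjusted over the list alone), with Klre1 at 3.28, Klrk1 at 3.63 and Klrb1c at 2.91. Of 8 helper and regulatory T cell markers 6 rose (median 2.71, adjusted p = 1.9e-06, adjusted p = 0.283 with an estimated correlation, 8 adjusted over the list alone), among them Ctla4 (3.93), Icos (3.25) and Ikzf2 (2.69). Cd4 had 4.41 ± 2.52 CPM in controls and 11.2 ± 6.65 CPM in the tumours labelled K17KO and did not pass (edgeR adjusted p = 0.1096). Without control tumour 23, the calls of Cd3e, Cd8a, Cd8b1, Gzmb and Ifng were lost (edgeR adjusted p = 0.083, 0.104, 0.107, 0.060 and 0.120), and that of Gzmb was lost without control tumour 24 (0.0503). Those of Cd8a, Cd8b1 and Ifng were also lost without control tumour 24 or 26 or tumour 28 or 29 (adjusted p from 0.062 to 0.108), and that of Cd3e without 24, 26 or 29 (0.062, 0.075 and 0.067). Control tumour 27 was the highest control for these 4 genes, and without it the log2 fold changes of Cd8a, Cd8b1, Cd3e and Ifng were 5.25, 6.15, 5.31 and 5.28.

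**Figure D2:**
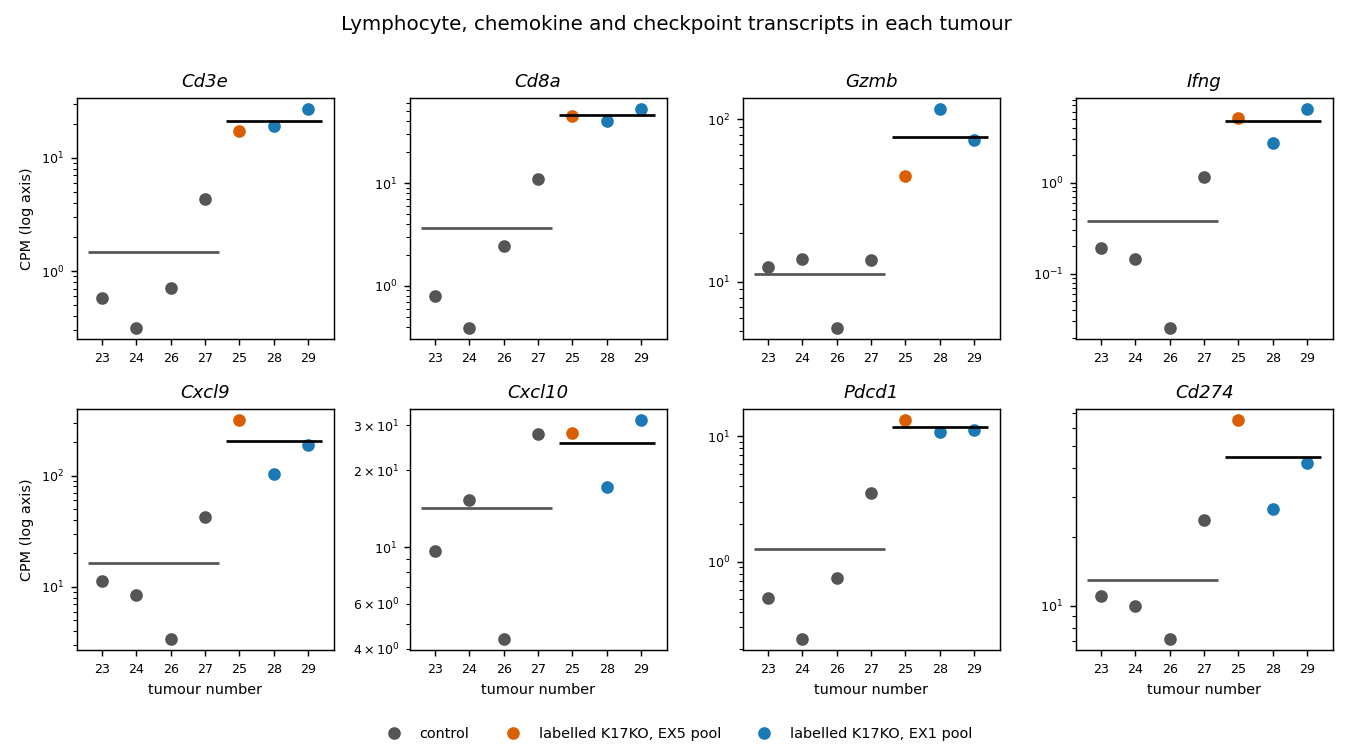
TMM-scaled CPM of 8 immune genes in each tumour, on log axes that differ between panels. Each point is 1 tumour and lines are group means. Cxcl10 overlapped between the groups, and of the control tumours, tumour 27 was highest for Cd3e, Cd8a, Ifng, Cxcl9, Cxcl10, Pdcd1 and Cd274.

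Interferon-gamma response and antigen presentation genes rose, and type I interferon response genes did not pass. Of 25 interferon-gamma response genes 16 rose (median 1.88, adjusted p = 1.15e-12, adjusted p = 0.283 with an estimated correlation, 23 adjusted over the list alone). Ido1, which degrades tryptophan, rose from 1.88 ± 0.720 to 24.8 ± 7.55 CPM (SD, log2 fold change 3.72 ± 0.38 SE, edgeR adjusted p = 0.0062) and Ubd, a ubiquitin-like modifier, by a log2 fold change of 5.38. None of the 26 type I interferon response genes was called (median −0.13, camera adjusted p = 0.615, 0.913 as the adjusted p with an estimated correlation, 0 adjusted over the list alone). Of 15 MHC class I genes 11 rose (median 1.44, adjusted p = 5.5e-09, adjusted p = 0.283 with an estimated correlation, 14 adjusted over the list alone). Among them were the proteasome subunits Psmb9 (2.53) and Psmb8 (1.69), the transactivator Nlrc5 (2.601) and H2-K1 (1.69). Of 10 MHC class II genes 8 rose (median 2.42, adjusted p = 3.1e-06, adjusted p = 0.287 with an estimated correlation, 9 adjusted over the list alone), including H2-Aa (3.29), H2-Eb1 (3.05) and H2-Ob (1.99).

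The chemokines Cxcl9 and Ccl5, which attract lymphocytes, and the chemokine receptor gene Cxcr6 were higher, although Cxcl10 was not called. Ccl5 is also a member of the cytotoxic lymphocyte list. Cxcl9, a ligand of CXCR3 (chromosome 5, 92321331 to 92328079), rose from 16.4 ± 17.7 to 204 ± 107 CPM (SD, log2 fold change 3.63 ± 0.83 SE, edgeR adjusted p = 0.026), and the call was lost without control tumour 23 (adjusted p = 0.091), 24 (0.074) or 26 (0.058) or tumour 29 (0.063), with a log2 fold change of 4.73 without control tumour 27. Ccl5 and Cxcr6 rose by 3.14 and 2.996. Cxcl10 had 14.3 ± 10.04 and 25.5 ± 7.42 CPM (log2 fold change 0.84 ± 0.55 SE, edgeR adjusted p = 0.276). Of 11 other chemokines, Ccl8 rose (3.11) and Ccl11, which attracts eosinophils, fell (−3.26), and the list was not called (median −0.06, adjusted p = 0.697, 0.855 as the adjusted p with an estimated correlation, 1 up and 1 down adjusted over the list alone). Of 10 CXCR2 ligands and inflammatory cytokines 6 rose (median 2.36, adjusted p = 6.0e-06, adjusted p = 0.243 with an estimated correlation, 8 adjusted over the list alone), among them Cxcl5 (2.21), Cxcl1 (3.86) and Il1a (3.49). Of 12 immune checkpoint genes 8 rose (median 2.08, adjusted p = 1.2e-05, adjusted p = 0.243 with an estimated correlation, 9 adjusted over the list alone). Pdcd1 (PD-1) rose by 3.22, Cd274 (PD-L1) by 1.78, Pdcd1lg2 by 4.04 and Lag3 by 2.38.

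Lists of markers of B and plasma cells, dendritic cells, macrophages, neutrophils and mast cells were also higher. Of 9 B and plasma cell markers 7 rose (median 2.55, adjusted p = 3.1e-06, adjusted p = 0.243 with an estimated correlation, 8 adjusted over the list alone), including Jchain (5.11), Igkc (5.12) and Mzb1 (3.998). Of 12 dendritic cell markers 7 rose and 2 fell (median 2.28, adjusted p = 0.0047, 0.283 as the adjusted p with an estimated correlation, 9 up and 2 down adjusted over the list alone). Batf3 (2.05), Xcr1 (3.19) and Ccl22 (3.19) rose, and Fscn1 (−0.83), which bundles actin, and Zbtb46 (−0.99), a transcription factor, fell. Of 15 macrophage and monocyte markers 3 rose, Ly6c2 (2.20), C1qc (0.92) and Ccr2 (1.17) (median 0.68, adjusted p = 0.0062, 0.341 as the adjusted p with an estimated correlation, 3 adjusted over the list alone). Ccr2 had a log2 fold change of 0.77 without tumour 29, and its call was lost without any 1 tumour other than 25 (adjusted p from 0.077 to 0.139). The macrophage score was 0.285 in tumour 28 and 0.293 in control tumour 27, so the groups overlapped. Adgre1 (F4/80) had 35.8 ± 12.9 and 59.4 ± 37.9 CPM (edgeR adjusted p = 0.265). Ptprc (CD45), carried by all leukocytes, rose from 88.0 ± 39.0 to 213 ± 70.9 CPM (log2 fold change 1.28 ± 0.36 SE, edgeR adjusted p = 0.045), with overlapping groups. Of 11 genes of classically activated macrophages 6 rose (median 1.84, adjusted p = 7.9e-05, adjusted p = 0.283 with an estimated correlation, 9 adjusted over the list alone), such as Cd86 (1.61) and Il6 (3.13). The list of alternatively activated macrophages was not called (4 of 11 rose, with Clec10a at 3.85, median 0.39, adjusted p = 0.147, 0.436 as the adjusted p with an estimated correlation, 5 up and 1 down adjusted over the list alone). Of 9 neutrophil markers 5 rose and Mmp9, a matrix protease, fell (median 1.47, adjusted p = 0.016, 0.283 as the adjusted p with an estimated correlation, 5 up and 1 down adjusted over the list alone), with Csf3r at 2.06, Cxcr2 at 1.62, S100a9 at 1.53 and Mmp9 at −2.20. Of 9 mast cell, basophil and eosinophil markers 5 rose (median 1.53, adjusted p = 3.6e-04, adjusted p = 0.283 with an estimated correlation, 8 adjusted over the list alone), including Cma1 (2.08), Mcpt4 (1.90) and Siglecf (1.78). Of 13 NF-kappaB targets 7 rose (median 1.05, adjusted p = 0.0013, 0.283 as the adjusted p with an estimated correlation, 7 adjusted over the list alone), among them Traf1 (2.04) and Tnfaip3 (1.35). In all, 17 of 20 immune lists were called upward at the preset correlation, and 0 lists were called with an estimated correlation (smallest adjusted p = 0.243). With tumour 25 left out, 16 lists of any kind were called upward at the preset correlation, against 21 with it, so not every immune list kept its call. The EX1 tumours 28 and 29, which take part in each of these contrasts, also stood apart in mitochondrial transcripts and Malat1, with values given under the comparison of the pools.

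Epithelial genes were higher in the tumours labelled K17KO, with levels that differed between the tumours. Of 12 keratins other than Krt17, 7 rose (median 5.07, adjusted p = 0.016, 0.283 as the adjusted p with an estimated correlation, 9 adjusted over the list alone). Krt6a rose from 0.139 ± 0.111 to 37.4 ± 31.1 CPM (SD, log2 fold change 8.01 ± 1.24 SE, edgeR adjusted p = 0.013), Krt16 by 6.94, Krt6b by 6.47 and Krt14 by 7.06. Tumour 29 held most of the Krt16, Krt6b and Krt14 transcripts, and without it the log2 fold changes were 3.49, 3.26 and 2.96, while Krt6a was 7.67. Krt8, a keratin of simple epithelia, had 1055 ± 216 CPM in controls and 1358, 245 and 58.3 CPM in tumours 25, 28 and 29 (edgeR adjusted p = 0.439). Of 21 epithelial adhesion genes 11 rose (median 3.09, and 3.09 with the gene absent from controls at its bound, adjusted p = 4.1e-04, adjusted p = 0.438 with an estimated correlation, 13 adjusted over the list alone). Epcam, an epithelial adhesion molecule, stood at 678 CPM in tumour 25, 13.1 in tumour 28 and 39.9 in tumour 29, against 0.730 ± 0.279 CPM in controls, and its log2 fold change was 5.15 without tumour 25. Dsp (desmoplakin) and Cldn1 rose by 7.70 and 3.77, and Dsp stood at 216, 3.10 and 219 CPM in tumours 25, 28 and 29. Of 8 keratinocyte differentiation genes 5 rose (median 4.79, adjusted p = 0.013, 0.436 as the adjusted p with an estimated correlation, 7 adjusted over the list alone), such as Tgm1 (3.05, and 1.66 without tumour 25), and tumour 29 had a list score of 6.07 against 1.51 and 1.11 in tumours 25 and 28. Krt10, a keratin of differentiated epidermis, had 371 CPM in tumour 29, 10.4 in tumour 28 and 2.30 in tumour 25, against 2.16 ± 0.314 CPM in controls, and its call was lost without tumour 29 (log2 fold change 1.54, edgeR adjusted p = 0.119). Without tumour 25, the lists of keratins and of epithelial adhesion genes were no longer called.

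Proliferation, hypoxia, muscle and unfolded protein response lists were lower, the last 3 with single tumours standing apart. Of 26 proliferation genes 12 fell (median −0.54, adjusted p = 1.2e-06, adjusted p = 0.243 with an estimated correlation, 17 adjusted over the list alone). Kif20a, a mitotic kinesin, fell from 100.1 ± 9.35 to 51.55 ± 2.49 CPM (SD, log2 fold change −0.95 ± 0.13 SE, edgeR adjusted p = 0.011), Tpx2 by a log2 fold change of −0.86 and Cdc20 by −0.77. Of 18 hypoxia and glycolysis genes 2 fell, Egln3 (−1.26) and Ero1a (−1.35) (median −0.58, adjusted p = 0.0050, 0.438 as the adjusted p with an estimated correlation, 1 adjusted over the list alone), and the glucose transporter Slc2a1 had 111 ± 19.7 and 48.4 ± 26.5 CPM (edgeR adjusted p = 0.059). Of 19 skeletal muscle markers 2 fell, Tnnt3 (−1.40) and Atp2a1 (−2.35) (median −1.48, adjusted p = 4.4e-05, adjusted p = 0.436 with an estimated correlation, 0 adjusted over the list alone), and Ckm had 8.50 ± 3.36 and 1.32 ± 1.15 CPM (edgeR adjusted p = 0.055). The muscle score was −4.40 in tumour 28, −0.76 in tumour 25 and −1.51 in tumour 29, against −1.04 in control tumour 24, and the median was −0.99 without tumour 28. Of 13 unfolded protein response genes 2 fell, Asns (−1.71), which makes asparagine, and the transcription factor Atf4 (−0.72) (median −0.33, adjusted p = 0.034, 0.464 as the adjusted p with an estimated correlation, 2 adjusted over the list alone). The score of this list was −0.445 in control tumour 26, against −0.423, −0.397 and −0.669 in tumours 25, 28 and 29. The call of the unfolded protein response genes was lost without control tumour 23, 24 or 27 or tumour 25 or 29 (adjusted p = 0.054, 0.0598, 0.059, 0.278 and 0.058), and that of the hypoxia and glycolysis genes without tumour 25 (adjusted p = 0.055).

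**Figure D3:**
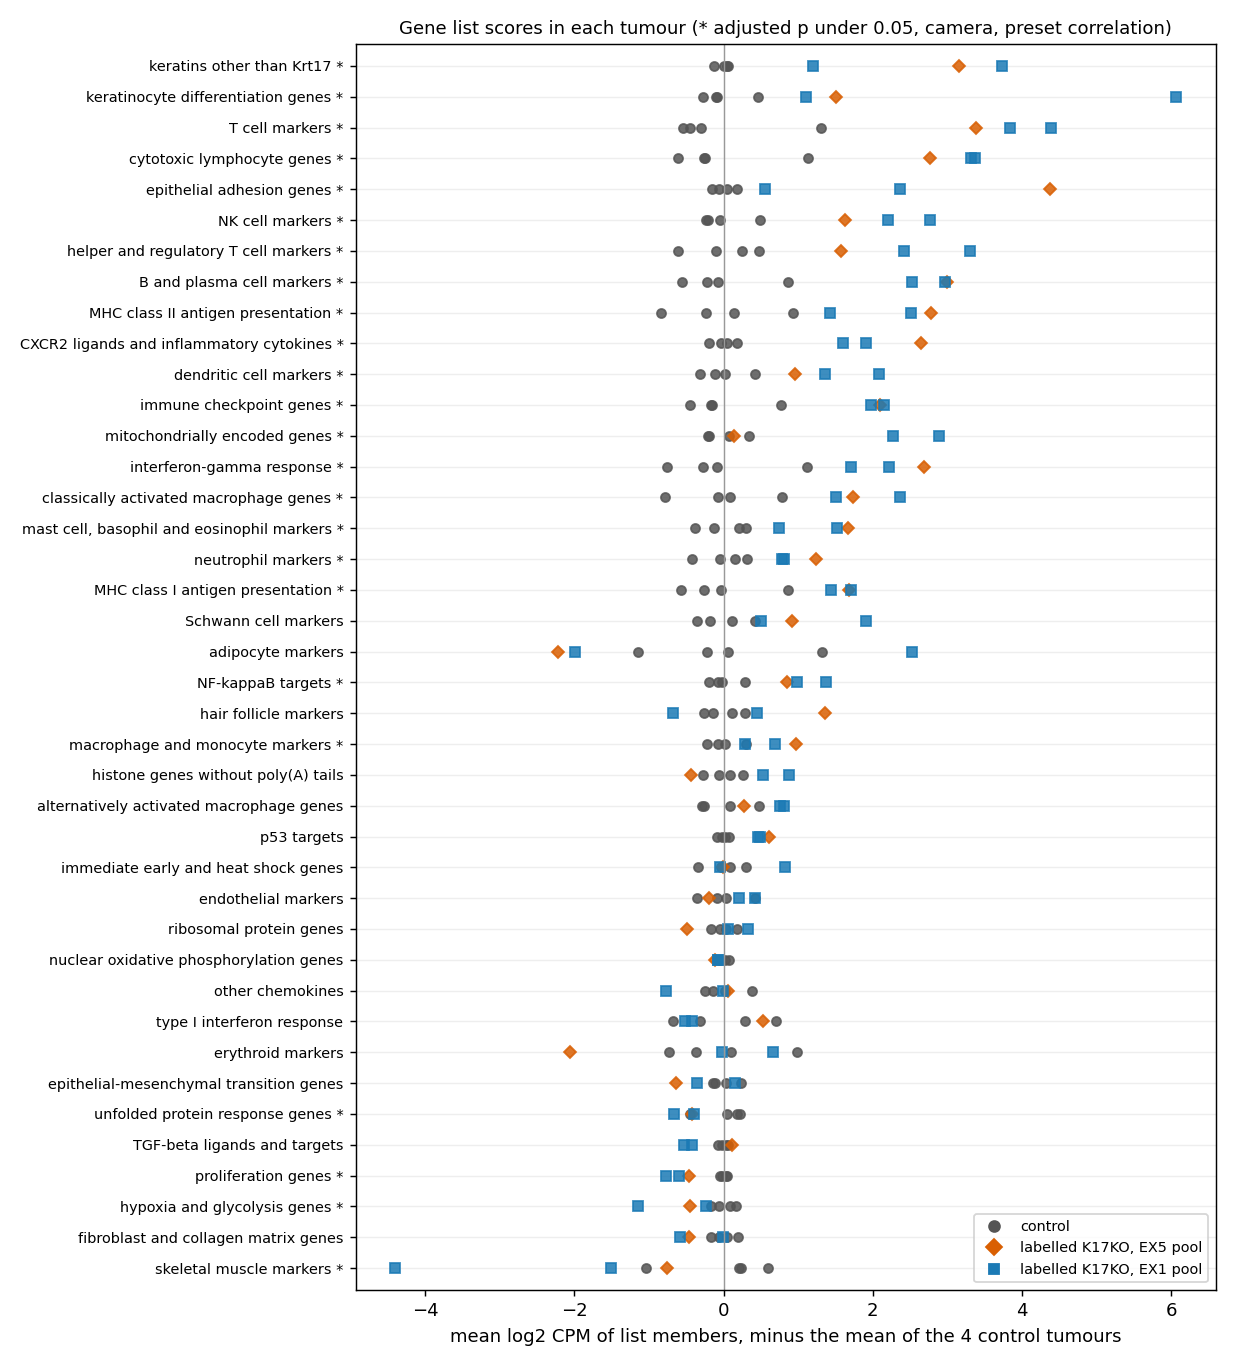
Score of the gene lists in each tumour, as the mean log2 CPM of its members minus the mean of the 4 control tumours, with lists ordered by median log2 fold change. Points are tumours, and a star marks lists called by camera at the preset correlation. All 3 tumours labelled K17KO lay above all 4 controls in T cell markers, while in mitochondrially encoded genes only the EX1 tumours 28 and 29 did.

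In all, camera called 25 of 41 lists, 21 upward and 4 downward. With an estimated correlation no list was called (6 with an unadjusted p under 0.05, smallest adjusted p = 0.243), and fry called 21. Fibroblast and collagen matrix genes were not called as a list (2 of 20 rose and 5 fell, median −0.62, adjusted p = 0.105, 0.422 as the adjusted p with an estimated correlation). Thy1 (2.49) and Dcn (2.35) rose, and Col5a1 (−1.16) and Fbln2 (−2.005) were among those that fell. Dcn stood at 2094 and 1063 CPM in EX1 tumours 28 and 29 and at 149 CPM in EX5 tumour 25, below the controls (168 to 252 CPM), and its log2 fold change was −0.53 with the EX5 tumour alone. The log2 fold change of Dcn was 1.48 without tumour 28, and its call was lost without any 1 tumour other than 25 (adjusted p from 0.107 to 0.155). None of the 14 endothelial markers was called (median 0.20, adjusted p = 0.697, 0.913 as the adjusted p with an estimated correlation).

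Camera did not call the remaining lists, while fry called p53 targets (adjusted p = 0.0036) and Schwann cell markers (adjusted p = 0.046). Of 13 p53 targets 4 rose, among them the death receptor Fas (2.14) and Pmaip1 (2.82), with a median of 0.28 (camera adjusted p = 0.189). Pmaip1 stood at 250 CPM in tumour 25, and its log2 fold change was 1.09 without that tumour. The call of Pmaip1 was lost without any 1 of the control tumours 23, 24, 26 and 27 (adjusted p from 0.072 to 0.104), and that of Fas without any 1 tumour other than 25 (adjusted p from 0.051 to 0.082). Of 12 epithelial-mesenchymal transition genes Snai1 fell (−1.63, median −0.25, adjusted p = 0.218). Fas, Pmaip1, Snai1, Thy1, Dcn, Col5a1, Fbln2, Ccl8, Ccl11, Clec10a, Fscn1, Zbtb46, Mmp9, Malat1 and Xist are given as examples chosen after their values were seen. Medians were 0.93 for 2 salivary gland markers (too few to test), 1.00 for 3 hair follicle markers, 1.15 for 9 adipocyte markers, 1.32 for 7 Schwann cell markers and −0.15 for 4 erythroid markers. They were −0.03 for 17 nuclear oxidative phosphorylation genes, −0.37 for 12 TGF-beta ligands and targets, 0.27 for 14 immediate early and heat shock genes and 0.51 for 8 histone genes. For 22 ribosomal protein genes the median was 0.08 and the mean 0.01, while camera pointed downward (adjusted p = 0.555).

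The EX1 and EX5 pools were compared to see whether tumours of the 2 edited pools resembled each other. By Pearson correlation of log2 CPM over all genes, EX5 tumour 25 was closer to each control (0.970 to 0.979) than to EX1 tumours 28 and 29 (0.959 and 0.949). Tumours 28 and 29 correlated at 0.975 with each other. Tumour 29 was slightly closer to tumour 25 than to any control (at most 0.947), and tumour 28 was not (0.959 to 0.966 with the controls). The EX1 tumours held far more mitochondrial RNA and the nuclear RNAs Malat1 and Xist, and the EX5 tumour held more epithelial adhesion transcripts and H19. Mitochondrially encoded genes took 8.53% and 6.49% of counts in EX1 tumours 28 and 29, 1.48% in EX5 tumour 25 and 1.19% to 1.71% in the controls. Of 13 mitochondrial genes 12 were called higher in EX1 (median log2 difference 2.30, camera adjusted p = 4.1e-14, adjusted p = 0.951 with an estimated correlation), and 12 of 13 also rose in K17KO against control (median 2.03, adjusted p = 5.4e-06, 0.378 as the adjusted p with an estimated correlation, 13 adjusted over the list alone), among them mt-Nd3 (2.86), mt-Nd4 (2.20) and mt-Co3 (2.10). Malat1 had 8652 and 7793 CPM in tumours 28 and 29, 611 in tumour 25 and 295 to 715 in controls. Of 23 epithelial adhesion genes 12 were lower in EX1 (median −2.41, adjusted p = 6.1e-09, adjusted p = 0.951 with an estimated correlation). Type I interferon response genes were lower in EX1 (4 of 26 called, median −0.99, adjusted p = 0.019, 0.951 as the adjusted p with an estimated correlation) and ribosomal protein genes higher (6 of 22 called, median 0.57, adjusted p = 0.0031, 0.951 as the adjusted p with an estimated correlation). Among the 5 lowest genes in EX1, H19, an imprinted long noncoding RNA, had 4507 CPM in tumour 25, 1.66 and 10.9 in tumours 28 and 29 and 108 to 190 in controls (log2 difference −9.57 ± 1.05 SE, edgeR adjusted p = 0.0038). Mcpt1 (−8.15) and Nexmif (−7.28) were also among them, and Myh3, with 2 counts over the EX1 tumours, had an EX5 to EX1 ratio of 193 (53.4 to 1592). The 5 highest were Fendrr (7.76 ± 0.89 SE, edgeR adjusted p = 0.0032), a long noncoding RNA, Tac1 (6.13), Rorb (5.80), Pappa2 (5.69) and Rxfp1 (5.25). Over 17495 genes, 4325 were called, 1610 higher and 2715 lower in EX1, and 804 genes were called in both comparisons. No list was called with an estimated correlation (1 of 42 with an unadjusted p under 0.05). The EX5 pool has 1 tumour, so the difference between pools and the difference between that tumour and the others are the same comparison. Y-linked transcripts separated the pools too, with 1828 and 3816 counts in EX1 tumours 28 and 29 and 0 in EX5 tumour 25. They were detected in control tumours 23 and 24 (931 and 1233 counts) but not in 27 (0 counts), with 1 count in 26. They stood at 65.96 and 139.04 CPM in tumours 28 and 29, against 29.82 and 29.87 CPM in control tumours 23 and 24.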

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

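The genes examined here were chosen in part after their values were seen, among them Malat1, Xist, Ccl8, Mmp9, Fscn1, Dcn, Fbln2, Clec10a, Fas and Pmaip1, and so were all 3 tests of the Krt17 level, the test of tumour cell share, the tests of the size of the immune list medians, the test of GC content and gene length as the whole cause of the pool difference and the test of chromosome 9. A Dixon test of the 4 control tumours marked a distant tumour in 19 of 162 groups. Esrp1 and Fxyd3, with no count in any control, are among the 162 but could not be marked. Chance alone marks about 1 in 20 groups only where values are normally distributed. Genes entered as CPM without a log, so that rate need not hold here. The comparison of 121 named genes and of the gene lists between the EX1 and EX5 pools marked 27 differences.

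Control tumour 27 held more of several T cell, B cell and interferon response transcripts than the other 3 control tumours. Its distance was 0.994 for Cd8b1, 0.901 for Cd3e, 0.853 for Ifng, 0.8496 for Pdcd1, 0.852 for Ccl5, 0.970 for Cxcr6, 0.857 for Ubd, 0.891 for Jchain, 0.978 for Igkc, 0.872 for Ccl8 and 0.869 for the T cell list score, and all were at the high end. All 11 values come from the same tumour, so they are not separate observations. Its NK cell list score (−0.214) was lower than in control tumours 23 (−0.0474) and 24 (0.491). Cd3e was 4.31 CPM in control tumour 27 and 17.4 CPM in tumour 25, the lowest of the tumours labelled K17KO, so the groups stayed apart.

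The EX1 tumours 28 and 29 differed from the EX5 tumour 25 in mitochondrial and nuclear RNA. The log2 differences were 2.56 for mt-Nd3, 2.26 for mt-Nd4, 2.12 for mt-Co3, 3.68 for Malat1, 2.18 for Xist and 2.30 for the median of the mitochondrial list, with 0.57 for the median of the ribosomal protein list. Malat1 and Xist lie on different chromosomes and both transcripts stay in the nucleus, and tumour 25 lay within the range of the controls for both. In the ribosomal protein score tumour 25 (−0.495) lay below every control. Whether handling of the tissue or its make-up set this apart cannot be told with these data.

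Epithelial transcripts and the single matrix genes Dcn and Fbln2 also separated the pools. The EX5 tumour 25 was higher in Epcam (−4.75), Krt8 (−3.22), Tgm1 (−2.58) and the median of the epithelial adhesion list (−2.41), and the EX1 tumours were higher in Dcn (3.34). Fbln2 was −1.96. With 1 EX5 tumour, a difference of pools and a difference of single tumours are the same thing here.

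The other differences between pools are given as values. Ntng1 was 4.23, Ctla4 2.07, Ccr2 1.25, Il6 2.50, Clec10a 2.85 and Fas 1.90. Nefl was −4.54, Car8 −2.62, Egln3 −0.92, Tnfaip3 −0.82, Mmp9 −1.78, Fscn1 −0.82 and Pmaip1 −3.02, and the median of the type I interferon list was −0.99. Among the controls, Pof1b and Ly6g6c in control tumour 26 and Ap1m2 in control tumour 23 had a distance of 1 because the other 3 control tumours had no count. Control tumour 26 was high for Snap25 (0.877) and low for Ccl22 (0.880), control tumour 24 was low for Epcam (0.847) and high for Malat1 (0.881), and control tumour 27 was low for Klrb1c (0.917).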

How the results depend on the processing

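The number of genes called between K17KO and control depended on single libraries. Leaving out each library in turn gave 64 (without control tumour 23) to 9018 (without tumour 25), against 3334. DESeq2 gave 5459, the libraries with Y-linked transcripts 6696, those without 473, and the mitochondrial covariate 1084. For Krt17 (5.07), leaving out each library gave 1.96 to 5.61, limma voom gave 3.34, the Y-linked covariate 4.62, libraries with Y-linked transcripts 5.79, those without 2.27 and the mitochondrial covariate 2.88. The Krt17 call was lost in these last 5 fits and without any single control tumour. Of 41 lists, 25 were called at the preset correlation, 0 with an estimated correlation and 18 to 28 with each library left out. The cause was not tested.

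Direction was reversed in 7 gene fits. In the libraries without Y-linked transcripts Krt8 was 0.37, Krt10 −0.0658 and Dcn −0.49. In the EX5 tumour alone Krt8 was 0.37 and Dcn −0.53, and with the mitochondrial covariate Krt8 was 0.14 and Dcn −0.66.

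List medians were reversed in 38 fits, and apart from the mitochondrial list these lists had not been called. With libraries left out in turn, type I interferon ranged from −0.75 to 0.15, other chemokines from −0.26 to 0.18, ribosomal from −0.17 to 0.24, endothelial from −0.0703 to 0.35, adipocyte markers from −3.38 to 1.90, histone genes without poly(A) tails from −0.00829 to 0.77 and erythroid from −0.87 to 0.78. In the libraries without Y-linked transcripts they were 0.37 for type I interferon, 0.28 for other chemokines, −0.54 for endothelial, −3.73 for adipocyte markers, 0.17 for TGF-beta, −0.0536 for mitochondrial, −0.42 for ribosomal and −0.59 for histone genes. In the EX5 tumour alone they were 0.47 for type I interferon, 0.43 for other chemokines, −0.35 for endothelial, −3.99 for adipocyte markers, 0.37 for TGF-beta, −0.51 for ribosomal and −0.62 for histone genes. With the mitochondrial covariate they were 0.52, 0.43, −0.39, −2.43, 0.22, −0.51 and −0.46 in the same order. Erythroid markers were 0.23 without a filter and 1.03 in the libraries with Y-linked transcripts, and ribosomal protein genes were −0.16 with the offset for GC content and length.

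Of the other gene fits 1621 kept direction and call, 620 were weaker and 13 stronger. Of the list fits 580 were the same, 55 weaker and 22 stronger. Of the pool gene fits 122 were the same and 6 weaker (Tac1, Mcpt1 and Myh3). The number of genes called between EX1 and EX5 ranged from 3088 to 5519 with each library other than tumour 25, the only EX5 tumour, left out. Totals of 25719888 to 41660819 counts per library leave genes of a few counts, such as Ap1m2 and Tll2 in the lower group, with wide intervals.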

Other observations

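Several transcripts fell strongly in the tumours labelled K17KO. Dmp1 fell from 345 to 5.46 CPM, Mycn from 23.2 to 1.40 CPM and the eosinophil attractant Ccl11 from 39.1 to 4.06 CPM, and all 3 kept the call without control tumour 23 or 24. Snai1, a repressor of epithelial genes, fell by a log2 fold change of −1.63 while Epcam, Dsp and Cldn1 rose, although the epithelial-mesenchymal transition list was not called. Mycn, Snai1 and Epcam in single tumour cells of both groups would show whether the change is in the tumour cells.

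Krt17 RNA was higher in all 3 libraries labelled K17KO. Keratinocytes of the skin could account for tumour 29. Its keratinocyte differentiation score exceeded the next highest library by 4.56, with Krt14 at 2667 CPM, Krt5 at 1715 CPM and Krt10 at 371 CPM. None of the 19 genes of the keratinocyte list is in another list and 5 of them exceeded 1 CPM in a control tumour. These levels, already seen when the test was written, cannot tell skin from tumour cells that make the same transcripts, so the source of Krt17 in tumour 29 stays open. In tumours 25 and 28 the smaller lower limit of the Krt17 to Krt5 ratio was 0.951, against an upper limit of 0.0846 in tumour 29. All controls exceeded that upper limit too (lower limits of 4.35 to 6.60), so the ratio alone cannot exclude skin beside Krt17 of other cells. At the ratio of tumour 29, the 36 and 71 Krt5 counts of tumours 25 and 28 bring few of their 300 and 93 Krt17 counts. Skin with another ratio was not tested. An exchange of 1 library of each group is argued against by all genes together. The 12 splits with such an exchange gave at most 3338 genes with an unadjusted p under 0.05, against 6411 with the labels. An exchange of all labels stays open. Edited transcripts may persist, and reads over the edited site or K17 protein in these tumours would tell a knockout from an exchange.

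Immune lists were higher in the tumours labelled K17KO. The T cell median exceeded the endothelial median by 3.59, with a pooled SD of 0.583 between list genes, not between tumours. This argues against a lower share of tumour cells that raises lymphocytes and endothelium alike as the whole cause. Control tumours 26 and 27 held 1 and 0 Y-linked counts, so the parental cells make few such transcripts. Y-linked levels were higher in tumours 28 and 29 (65.96 and 139.04 CPM) than in control tumours 23 and 24 (29.82 and 29.87 CPM). These levels could reflect a larger share of host cells in the EX1 tumours, so a part of the cause stays open. Xist was higher in the same tumours too, at 1378 and 1423 CPM against 145 and 352 CPM, and so was Malat1. The Y-linked levels can therefore not be told apart from the shift of these libraries in nuclear RNA, and they do not measure the host share. Tumour 25 held 0 Y-linked counts, so its host share cannot be read this way. The T cell median exceeded the fibroblast median by 4.41. That list decides nothing, because tumour cells may make such transcripts, and Col3a1 was among the top genes of every control tumour. Of 17 called lists, 17 stayed called upward with the mitochondrial covariate and 17 with the Y-linked covariate, but kept calls decide little where other splits call as many lists. With the Y-linked covariate 17 of 17 lists kept at least 0.5 of their median. This fit decides little, because tumours with and without Y-linked transcripts were present in both groups and the covariate could take little from the medians. That presence in both groups, rather than the fit, argues against Y-linked status as the whole cause. With the mitochondrial covariate 15 of 17 did, and 51 of 112 named genes kept their call. Tumour 25 was the single library labelled K17KO inside the control range of the mitochondrial score, so that source stays open. With an estimated correlation 0 lists were called without a covariate (smallest adjusted p = 0.243). Chance could not be excluded for the number of lists, because 9 of 35 ways to split the libraries gave at least 25 lists and the highest other split gave 30. For genes, 1 of 35 splits, the real one, gave as many calls, and the highest other gave 0. At an unadjusted p under 0.05 the real split gave 6411 genes and the highest other 3338. Counting of CD8 T cells in sections of more tumours per pool, with the sex of each host recorded, could test this.

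The pools differed in 4325 genes. Correction for GC content and gene length left 3984 genes called, so the trends that this offset removes are not the whole cause. All 10 named pool genes stayed called, but they were picked for the largest differences, so this decides nothing. The correction kept 77.2% of the calls, between the limits of 50% and 80% set for a decision, so a part in single genes stays open. Between control tumours with and without Y-linked transcripts edgeR called 0 genes (553 at an unadjusted p under 0.05), but it called none of the 4 Y-linked genes either, so this count decides nothing. Over the genes called between the pools, the difference between these control tumours had a median of 0.0295 and an upper quartile of 0.129 of the pool difference. This argues against Y-linked status as the whole cause, and a smaller part stays open. More EX5 tumours would be needed to separate pool from tumour.

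Copy number differences between the injected cell populations were looked for in windows of 50 neighbouring genes. The smallest of the most extreme medians in libraries labelled K17KO was 0.738, against 0.598 in the most extreme control. These windows decide nothing for the 3 tumours together, because the same stretches of chromosomes 1 and 6 were the most extreme in control libraries and the stretch on chromosome 6 holds 6 genes of the immune lists. The outcome was first set to count as a fit and was changed to undecided after the windows were seen. In simulated data shifts of 1 and 2 SD were recovered and 0.5 SD was not, and the requirement for 0.5 SD was dropped after it failed.

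Chromosome 9 stood higher in the EX1 tumours, in a test chosen after the windows were seen. Outside the gene lists, the median over 834 genes of chromosome 9 was 0.512 in tumour 28 and 0.415 in tumour 29 (largest values of shuffled genes 0.208 and 0.242). It was 0.0823 in EX5 tumour 25, and the largest chromosome median of a control tumour was 0.199 in size. All 17 windows of chromosome 9 were above 0 in both EX1 tumours, with lowest values of 0.391 and 0.178. Chromosome 19 had medians of 0.398 and 0.319 in these tumours and chromosome 2 had −0.274 and −0.255. Exceeding shuffled genes was not particular to these tumours, as tumour 25 did so on chromosome 8 (0.223 against 0.101), control tumour 27 on chromosome 3 (0.199 against 0.0710) and control tumour 26 on chromosome 16 (0.183 against 0.0614) and chromosome 9 (−0.111). The medians of chromosomes 9, 19 and 2 in both EX1 tumours were larger in size than any chromosome median of the other 5 tumours (at most 0.223). A gain of chromosome 9 in the EX1 cells is a candidate explanation, and it could account for small shifts of its genes between the pools. Cd3e, which lies there, rose far more than these medians against the controls (log2 fold change 3.83). Between the pools it differed by only 0.34 (edgeR adjusted p = 0.874). In simulated values for this test (14163 genes) a shift of 0.5 SD was recovered. DNA sequencing of the injected cells could settle it.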
